A study of Homo sapiens with 6 samples.

How the data were processed

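RNA from 3 control and 3 PEG10 knockdown samples of the choriocarcinoma line JEG3 was made into strand-marked mRNA libraries and sequenced as paired-end reads on an Illumina HiSeq instrument, per the labels' protocols. Per the submitters' processing notes, TopHat 1.4.1 (an aligner) and Cuffdiff 2.2.0 (which estimates and compares transcript abundance) were used with build hg19. The deposited values are FPKM, fragment numbers scaled by transcript length and by the library's mapped fragments, per gene and per library, per the file headers. The annotation release, the strand setting of the counting, the scaling between libraries that Cuffdiff offers and any filter are not given in the sources used here. Because the strand setting is not given, the values of genes that overlap or lie antisense to one another are uncertain. FPKM are estimates divided by length and by the library total, so they carry no read counts, a strong change in a few abundant genes shifts all others, and a value of 0 can be a failed estimate.

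The deposited table held 57150 genes with Ensembl identifiers and hg19 loci, and 1 row with no entries, which was left out. Of the genes, 30486 were at 0 in all 6 libraries. Each column matched the label of 1 sample by its name, and 0 columns belonged to other samples. A locus in the table is the stretch of overlapping genes that was handled together, and 67.8% of the tested genes shared theirs with another gene. Locus starts were taken as counted from 0, since in 21500 of 51307 genes with a reference length the end minus the start equalled the gene length of the reference annotation, against 331 for the other convention; printed starts are counted from 1. The reference annotation was GENCODE release 29 on another build, and it was used by gene identifier for lengths, GC content and 3' UTR sequences, with no coordinates taken from it. Absolute depth is unknown. Among values under 0.3 FPKM the spacing of the values gave the relative depth of each library.

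Tests ran on log2(FPKM + 1) for the 12652 genes with a mean FPKM of at least 1 over the 6 libraries, with limma 3.58.1 in R 4.3.3 (limma-trend, moderated test, group as the only term) and Benjamini-Hochberg adjustment over all genes tested, with 0.05 as the threshold. All adjusted p-values of single genes come from limma. Fold changes and standard errors are on the log2(FPKM + 1) scale, which understates the change of low genes, while group values are means and SDs of FPKM. Of the tested genes 132, and of the changed genes 8, were listed at 0 in at least 1 library. PEG10 also had an exact two-sided permutation test, whose smallest p with 3 against 3 samples is 0.1. The samples carry replicate numbers 1 to 3 in both groups, but nothing in the labels says that a number marks a shared culture or day, so no block was used in the main test.

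Before the data were examined, 25 gene lists were fixed from textbook knowledge of trophoblast, imprinting, the TGF-beta family, the cell cycle, stress responses and other cell types, and 24 were tested. The list of mitochondrially encoded genes was not analysed here. Lists were tested with camera from limma at a preset correlation of 0.01 between genes, with the correlation estimated per list, and with fry, which asks whether a list's own genes move one way on balance and does not compare them with other genes; p-values were adjusted over the 24 lists. Of the 5 lists that passed at the preset correlation, 0 passed with an estimated one. That estimate used the 6 libraries without a GC correction, so it can carry the GC trends between them that are described below. How far these trends affect it was not tested. Counts of changed members are given over all genes tested and adjusted over the list alone. The genes named in the text were chosen by a rule fixed at the same time: PEG10 and a panel of 10 genes whatever their result, the 10 largest rises and the 10 largest falls among changed genes whose groups did not overlap, the 5 changed genes with the highest mean FPKM in each direction, and up to 4 changed members of each list with the smallest p. COL3A1 and PTPRC, and the genes at the start of the other observations, were named after their values were seen.

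The test was checked on data simulated from these 6 libraries with 12652 genes, of which 50 at each size were changed. It recovered 34% of the genes changed 1.5-fold, 66% at 2-fold, 96% at 4-fold and 98% at 8-fold, and 6.37% of its calls were false. The simulated noise was independent between genes, without the GC trends of these libraries. Only better expressed genes were changed, and fewer than were called in the real data. These rates may therefore not hold for the real comparison. Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a filter at 5 FPKM, median-of-ratios rescaling, quantile normalization, the replicate number as a block, robust moderation, no intensity trend, a fold threshold of 1.5, the other list tests and leaving out each library in turn. Added after seeing the data were library weights from limma, a test without genes whose 3' UTR carries either of 2 sequences of 7 bases (PEG10, a carrier, was kept), and a GC correction, which removed from each library a loess trend (span 0.5) of the deviation from the gene mean on transcript GC content. A GC value was available for 12300 of the tested genes (97.2%). The 7-base test regressed GC-corrected fold changes on the presence of each 7-mer in the 3' UTR after removal of UTR length and composition. It used UTRs of at least 50 bases and 7-mers found in at least 100 genes. The extremes were compared with 100 permutations of the fold changes across genes. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served for these steps and the figures.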

Results

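The data were gene expression values from RNA sequencing of JEG3 cells, a human choriocarcinoma line that keeps features of placental trophoblast and secretes chorionic gonadotropin. The study asked what PEG10, a paternally expressed imprinted gene derived from a retrotransposon and needed for placental development, does in this line. Libraries from 3 control and 3 PEG10 knockdown samples were compared. The labels name the second group a knockdown while the series title speaks of a knockout, and the extraction text speaks of placenta while the source is given as choriocarcinoma. The groups are called control and knockdown here, and the reagent used is not given in the sources used here. Nothing in the labels says that the 3 samples of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Values were FPKM, fragment numbers scaled by transcript length and library total, and carry no read counts. FPKM summed to between 708713 and 747065 per library, and the number of genes with at least 1 FPKM lay between 12531 and 12594. Absolute depth is unknown. The spacing of the lowest values put the relative depth of the libraries between 0.837 in control replicate 3 and 1.10 in control replicate 1, with knockdown replicate 1 set to 1.

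PEG10 itself was checked first. Its level fell from 104 ± 7.15 FPKM in control cells to 19.9 ± 1.87 FPKM in knockdown cells (SD, n = 3 each), which left 19.2% of the control level. The control libraries held 97.3, 111 and 102 FPKM and the knockdown libraries 21.7, 20.1 and 17.9 FPKM, so the labels and the targeted gene went the same way in each of the 6 libraries. On the log2(FPKM + 1) scale the change was -2.32 with a standard error of 0.11 (limma adjusted p = 6.00e-04). An exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 samples allow. PEG10 (ENSG00000242265) lies on chromosome 7 at 94285637 to 94299007 in build hg19, and the value covers its whole gene locus. SGCE, the imprinted gene that lies next to PEG10 and is transcribed in the opposite direction, held 7.99 ± 1.36 FPKM in control and 8.79 ± 0.27 FPKM in knockdown cells, a log2 difference of 0.13 ± 0.13 (SE) that did not pass (limma adjusted p = 0.548) and turned to -0.21 after a correction for GC content.

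Knockdown cells carried more mRNA for CGA, a placental hormone subunit, and less for HAND1, a transcription factor of early trophoblast. Of 12652 genes tested, 1013 changed, 493 of them higher and 520 lower in knockdown cells (limma adjusted p below 0.05), and 694 changed by at least 1.5-fold, 342 higher and 352 lower. HAND1 (ENSG00000113196, chromosome 5, 153854532 to 153857824) fell from 31.0 ± 9.63 to 2.93 ± 0.69 FPKM, a log2 change of -2.9996 ± 0.23 (SE; adjusted p = 0.00177). CGA (ENSG00000135346, chromosome 6, 87795216 to 87804824), which encodes the alpha subunit shared by the glycoprotein hormones, rose from 397 ± 99.97 to 1603 ± 226 FPKM, a log2 change of 2.03 ± 0.20 (SE; adjusted p = 0.00421). For HAND1 and CGA, control replicate 3 lay furthest of the controls from the knockdown libraries. It held 41.9 FPKM of HAND1, against 23.7 and 27.4 in control replicates 1 and 2, and 283 FPKM of CGA, against 466 and 444. The groups did not overlap in 4686 of the tested genes (37.0%), and 3401 genes passed at an unadjusted p below 0.05. A single gene would show no overlap in 10% of cases if the libraries were exchangeable. Genes are not independent, and the share was not computed for other splits of the libraries, so the excess over 10% has no test.

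**Figure D1:**
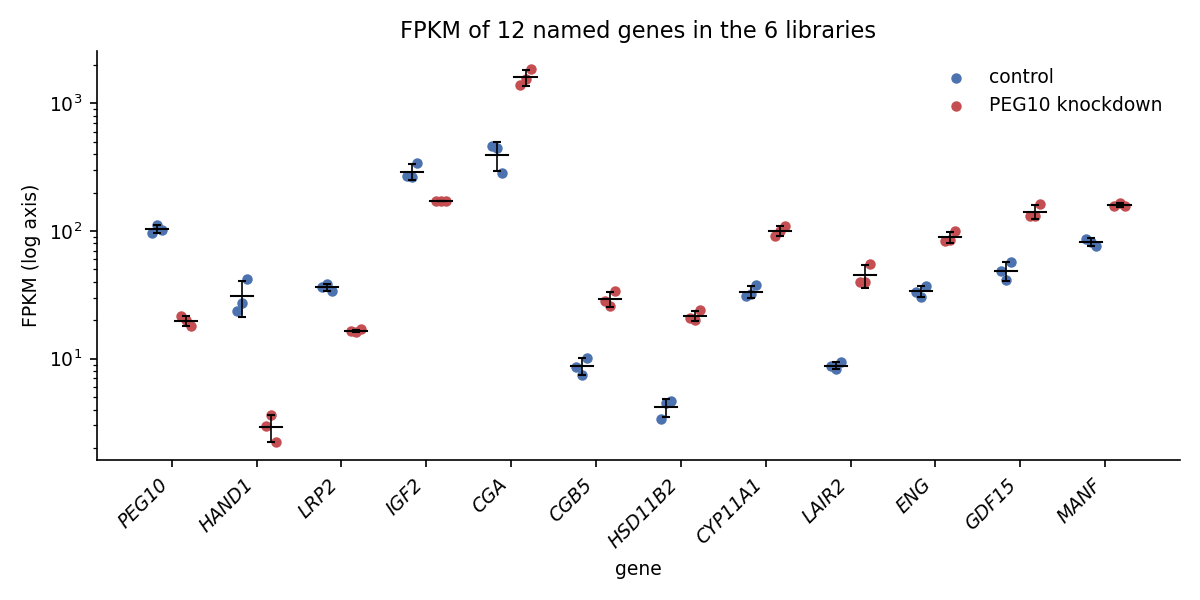
FPKM (log axis) of 12 named genes in each of the 3 control (blue) and 3 PEG10 knockdown (red) libraries, with the horizontal bar at the group mean and the error bar 1 SD. PEG10 fell from 104 to 19.9 FPKM and HAND1 from 31.0 to 2.93 FPKM, while CGA rose from 397 to 1603 FPKM. The groups did not overlap in the 12 genes, which holds for all 1013 changed genes, from which the 12 were taken.

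WIPF1, which binds the actin regulator WASP, gave the largest rise outside genes listed at 0 (4.31 ± 0.22 to 26.3 ± 7.17 FPKM). LAIR2, a secreted collagen receptor of invasive trophoblast, rose from 8.84 ± 0.53 to 45.1 ± 8.97 FPKM and TPPP3, a tubulin-binding protein, from 2.56 ± 0.36 to 15.2 ± 1.79 FPKM. HSD11B2, the enzyme that inactivates cortisol in the placenta, rose from 4.16 ± 0.68 to 21.6 ± 2.03 FPKM, and INSL4, a placental peptide of the insulin family, from 3.39 ± 0.42 to 16.8 ± 1.84 FPKM. CRIP2, a LIM domain protein, rose from 9.67 ± 2.19 to 36.2 ± 4.77 FPKM, and SAT1, the enzyme that starts polyamine breakdown, from 31.5 ± 3.09 to 112 ± 10.4 FPKM. Their log2 changes lay between 1.80 for SAT1 and 2.33 for WIPF1. After HAND1 and PEG10, the largest falls were in SLC4A8, a bicarbonate transporter (11.2 ± 1.49 to 2.11 ± 0.32 FPKM), CRYAB, a small heat shock protein (29.2 ± 4.78 to 6.85 ± 0.25 FPKM), and MYOZ1, a protein of the muscle Z-disc (8.996 ± 2.60 to 1.62 ± 0.50 FPKM). ANGPTL2, a secreted angiopoietin-like protein, fell from 3.19 ± 1.18 to 0.128 ± 0.014 FPKM, and LAYN, a hyaluronan receptor, from 8.24 ± 1.24 to 1.58 ± 0.11 FPKM. These falls lay between -1.84 for LAYN and -1.97 for SLC4A8 on the log2 scale.

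The rule for the largest changes also named 5 short or non-coding genes that were listed at 0 in all libraries of 1 group, where a 0 can be a failed estimate, so no fold is given. SCARNA23 was listed at 0 in the 3 control libraries and at 15.9, 21.3 and 24.7 FPKM in the knockdown libraries, and CTA-276O3.4 at 0 in the controls and at 3.76, 2.13 and 4.40 FPKM after knockdown. The opposite held for 3 small RNAs, each listed at 0 in the knockdown libraries. In the controls SCARNA18 was listed at 11.98, 13.5 and 38.0 FPKM, SNORD118 at 10.2, 4.73 and 37.7 FPKM and SNORA22 at 9.16, 10.5 and 20.0 FPKM. Among abundant genes, CALR and SQSTM1, a chaperone of the endoplasmic reticulum and an autophagy receptor, rose from 647 ± 77.1 to 879.6 ± 19.1 FPKM and from 578 ± 76.6 to 807 ± 44.03 FPKM. COX7C, a subunit of respiratory complex IV, rose from 433 ± 18.3 to 867 ± 19.4 FPKM (log2 change 1.00), and the ubiquitin gene UBC rose from 497 ± 29.6 to 715 ± 18.4 FPKM. TUBA1B, an alpha-tubulin, fell from 1667 ± 335 to 778 ± 89.2 FPKM, TPM1, a tropomyosin, from 817 ± 21.1 to 606 ± 18.9 FPKM and HNRNPC, an RNA-binding protein, from 771 ± 4.06 to 603 ± 25.7 FPKM. RN7SL2, the RNA of the signal recognition particle, fell from 8840.2 ± 339.7 to 7134 ± 216 FPKM and RPS18, a ribosomal protein gene, from 3992 ± 180.5 to 3037 ± 202 FPKM. TUBA1B, HNRNPC, RPS18 and RN7SL2 have near-identical copies in the genome, between which reads can be split, so their values are uncertain.

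Of the genes fixed for reporting whatever their result, CGA, CGB5 and GCM1 rose. CGB5 (ENSG00000189052, chromosome 19, in a shared locus at 49526126 to 49552400), a beta subunit gene of chorionic gonadotropin, went from 8.74 ± 1.33 to 29.4 ± 3.98 FPKM (log2 change 1.64, adjusted p = 0.00309). Its neighbours are near-identical copies, so the value of a single copy is uncertain; the summed FPKM of the family went from 35.4 ± 5.49 to 111 ± 19.2, a ratio of 3.15. GCM1, a transcription factor of trophoblast fusion, went from 66.9 ± 7.14 to 110.5 ± 8.68 FPKM (log2 change 0.72, adjusted p = 0.0159), but missed the threshold when any 1 library other than control replicate 3 was left out. Another 5 did not pass. ERVW-1, the syncytin-1 gene, held 14.6 ± 1.84 FPKM in control and 22.8 ± 4.43 FPKM in knockdown cells (adjusted p = 0.0711). CDKN1A, a cell cycle inhibitor, held 137 ± 25.03 and 188 ± 8.34 FPKM (adjusted p = 0.0805), and ID1, a BMP target, 13.2 ± 3.26 and 8.50 ± 0.92 FPKM (adjusted p = 0.0985). For HLA-G, an HLA molecule of invasive trophoblast, the values were 37.8 ± 4.26 and 45.8 ± 2.84 FPKM (adjusted p = 0.171), and for MKI67, a proliferation marker, 63.5 ± 11.98 and 70.3 ± 6.21 FPKM (adjusted p = 0.536). Without control replicate 3 the log2 differences of CDKN1A (0.61), ID1 (-0.39) and HLA-G (0.36) passed, and that of MKI67 was -0.0039. After the GC correction ERVW-1 passed too (0.59). ACVRL1, a receptor for BMP9, lay below the expression filter, listed at 0 in the 3 controls and at 0.115, 0.094 and 0.282 FPKM in the knockdown libraries.

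Of 31 measured syncytiotrophoblast and placental hormone genes, 19 rose, 0 fell and 12 did not pass, with a median log2 change of 0.84. CYP11A1, which makes pregnenolone from cholesterol, went from 33.5 ± 3.48 to 100.3 ± 8.54 FPKM beside the rises of INSL4, HSD11B2 and CGB5. The list stood apart from other genes with camera at a preset correlation (adjusted p = 2.89e-12), but not with an estimated correlation (adjusted p = 0.348 with an estimated correlation). For this and the other lists, that estimate came from the 6 libraries without a GC correction. Of the members, 23 were higher and 2 lower when adjusted over the list alone. Control replicate 3 differed from each of the other libraries in its relation to GC content, and knockdown replicate 1 differed less strongly from the remaining ones. Without control replicate 3, 21 members were higher and 1 lower. In that setting the calls over all 12652 genes rose too, from 493 to 1767 higher and from 520 to 1375 lower. The larger counts without that library, here and in the lists below, are therefore in part a general rise in calls. Families of near-identical copies made up 9 of the 31 members.

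Among 39 measured genes of the unfolded protein and ATF4 responses 11 rose, 1 fell and 27 did not pass. MANF, a secreted protein of endoplasmic reticulum stress, rose from 82.2 ± 5.26 to 160.6 ± 5.85 FPKM, and GDF15, a stress-induced TGF-beta family hormone, from 49.1 ± 8.08 to 142 ± 17.9 FPKM. DDIT4, an inhibitor of mTORC1, rose from 30.9 ± 2.93 to 62.1 ± 3.48 FPKM and MTHFD2, a mitochondrial folate enzyme, from 72.3 ± 5.31 to 123 ± 2.95 FPKM. The list passed with camera (adjusted p = 1.88e-05), and not with an estimated correlation (adjusted p = 0.348 with an estimated correlation). The higher and lower counts were 22 and 2 adjusted over the list alone. Without control replicate 3 they were 27 and 3 over all genes tested. GDF15 is also in the lists of hormone genes and of the TGF-beta superfamily, and DDIT4 in the hypoxia list.

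Of 31 measured hypoxia-responsive genes 5 rose, 1 fell and 25 did not pass. ADM, the vasodilator adrenomedullin, rose from 42.7 ± 2.03 to 95.7 ± 5.39 FPKM and KDM3A, a histone demethylase, from 15.9 ± 4.10 to 30.5 ± 1.34 FPKM, while SLC2A3, a glucose transporter, fell from 479 ± 16.5 to 377 ± 7.18 FPKM. Camera gave adjusted p = 0.0427, and adjusted p = 0.348 with an estimated correlation; adjusted over the list alone 7 were higher and 2 lower. The call was lost without control replicate 1 (adjusted p = 0.0558), control replicate 2 (0.0640) or knockdown replicate 1 (0.0726), and without control replicate 3 the list passed with 12 members higher and 2 lower.

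Of 32 measured extravillous trophoblast and invasion genes 9 rose, 2 fell and 21 did not pass. Beside LAIR2, CDH5, the cadherin of endothelium and of trophoblast that lines vessels, rose from 13.3 ± 0.48 to 36.9 ± 3.21 FPKM, the adhesion molecule MCAM from 3.98 ± 0.42 to 16.4 ± 2.24 FPKM and the membrane metalloproteinase MMP15 from 9.74 ± 1.37 to 21.1 ± 1.11 FPKM. Camera gave adjusted p = 8.31e-05, and adjusted p = 0.373 with an estimated correlation. It held 14 higher and 2 lower members adjusted over the list alone, and 16 and 2 over all genes tested without control replicate 3.

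Genes of cytotrophoblast and trophoblast stem cells held 0 higher and 5 lower members of 32. Beside HAND1, LRP2, the endocytic receptor megalin, fell from 36.4 ± 2.42 to 16.5 ± 0.43 FPKM. PAGE4, a cancer/testis antigen family member expressed in placenta, fell from 10.2 ± 1.78 to 5.75 ± 0.49 FPKM and TEAD4, a transcription factor of trophoblast identity, from 45.9 ± 7.15 to 29.2 ± 2.16 FPKM. As a list they did not pass with camera (adjusted p = 0.0738, and adjusted p = 0.373 with an estimated correlation), but did, downwards, with no filter (0.0113) and under quantile normalization (0.0431). When adjusted over the list alone, 0 were higher and 8 lower, but without control replicate 3 the counts over all genes tested were 7 higher and 10 lower.

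Other imprinted genes moved in both directions. Among 16 paternally expressed genes 3 rose and 1 fell (camera adjusted p = 0.207). IGF2, the fetal growth factor, fell from 291 ± 41.6 to 172 ± 0.57 FPKM. AIM1 (7.84 ± 2.18 to 16.2 ± 2.41 FPKM), MIMT1 (1.85 ± 0.18 to 3.35 ± 0.48 FPKM) and PXDC1 (53.3 ± 6.11 to 72.9 ± 3.18 FPKM) rose. Of 15 maternally expressed genes 1 rose and 0 fell (adjusted p = 0.380). That gene, the protease inhibitor TFPI2, held 0.55 ± 0.05 and 1.67 ± 0.37 FPKM. It was also the 1 of 13 measured neighbours of PEG10 at 7q21 to pass, and the neighbours did not pass as a list (adjusted p = 0.560). TFPI2, MIMT1 and the histone gene HIST1H2AC missed the threshold after the correction for GC content. Of 6 measured genes that, like PEG10, derive from retrotransposon gag, MOAP1 (10.1 ± 0.16 to 6.98 ± 0.39 FPKM) and PNMA1 (11.2 ± 1.27 to 7.42 ± 0.29 FPKM) fell and 0 rose. The list passed with camera (adjusted p = 0.00626; adjusted p = 0.373 with an estimated correlation), missed the threshold without control replicate 3 (0.0504), and held 4 lower members adjusted over the list alone. Both genes carry in their 3' UTR a 7-base sequence that was more frequent among lower genes, and without the carriers of such sequences the list gave camera adjusted p = 0.167. That test took out both changed members, and the sequences were picked from these same fold changes. The lost call therefore cannot tell whether the sequences account for the falls. Adjusted over the list alone, 3 paternally expressed genes were higher and 1 lower, 1 and 0 of the maternally expressed genes, and 1 and 0 of the neighbours. Over all genes tested without control replicate 3, the counts were 5 and 1, 3 and 1, and 2 and 2.

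In the TGF-beta superfamily, 5 of 18 receptors, ligands and SMADs rose and 1 fell. ENG, the co-receptor endoglin, rose from 33.7 ± 3.42 to 89.6 ± 9.53 FPKM, TGFB1 from 6.90 ± 1.48 to 17.0 ± 2.48 FPKM and TGFBR3, the co-receptor betaglycan, from 31.04 ± 4.87 to 49.98 ± 3.84 FPKM. The list as a whole did not pass (camera adjusted p = 0.713), with a mean log2 difference of 0.14 and a median of -0.01, and its direction turned without control replicate 3. Among 20 target genes of TGF-beta and BMP signals 4 were higher and 1 lower (adjusted p = 0.460): KLF10 (12.8 ± 0.98 to 20.5 ± 1.36 FPKM), SERPINE1 (13.7 ± 1.03 to 25.7 ± 4.88 FPKM) and BHLHE40 (45.4 ± 4.72 to 67.99 ± 3.75 FPKM) rose, and ID2, a BMP target, fell from 38.7 ± 3.19 to 27.7 ± 1.05 FPKM. Adjusted over the list alone, 5 members of the superfamily were higher and 4 lower, and 6 of the targets were higher and 4 lower. Over all genes tested without control replicate 3, the counts were 5 and 5 for the superfamily and 7 and 2 for the targets.

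Of 42 S phase genes 4 rose and 1 fell, and without control replicate 3 there were 10 higher and 7 lower. RRM2, a subunit of ribonucleotide reductase, rose from 258 ± 12.4 to 437 ± 36.9 FPKM and the flap nuclease gene FEN1 from 88.2 ± 1.66 to 116 ± 1.197 FPKM. The G1/S cyclin genes CCNE1 (278 ± 20.7 to 405 ± 11.2 FPKM) and CCNE2 (4.36 ± 2.26 to 15.1 ± 1.95 FPKM) rose too. The list did not stand apart from other genes (camera adjusted p = 0.606), with a direction that turned under quantile normalization, while its own genes moved upwards on balance with fry (adjusted p = 0.0278). Of 40 G2 and M phase genes 0 passed in either direction (adjusted p = 0.778), and without control replicate 3 there were 2 higher and 9 lower. BTG2, an antiproliferative p53 target, rose from 67.6 ± 9.85 to 117 ± 0.52 FPKM as the 1 of 26 p53 targets to pass with all libraries (camera adjusted p = 0.0738, and 0.00411 upwards with fry). Without control replicate 3, 8 p53 targets were higher and 1 lower, and with no filter the list passed upwards (camera adjusted p = 0.0159; with an estimated correlation and the filter, 0.348). Of 31 apoptosis regulators 3 rose and 1 fell (camera adjusted p = 0.391, and 0.0329 upwards with fry). The executioner caspase gene CASP7 (7.81 ± 0.81 to 12.8 ± 0.25 FPKM) and the survival genes MCL1 (109.96 ± 4.79 to 145 ± 6.36 FPKM) and BCL2L2 (14.9 ± 0.39 to 20.4 ± 1.14 FPKM) rose. CASP6 fell from 13.7 ± 1.13 to 8.93 ± 0.86 FPKM. ODC1, the first enzyme of polyamine synthesis, fell from 165 ± 8.96 to 114 ± 11.6 FPKM and was the 1 changed member of 35 MYC target and ribosome biogenesis genes (adjusted p = 0.183). Of 23 replication-dependent histone genes 4 rose and 1 fell, while the list's median was -0.20 (adjusted p = 0.380). HIST1H2BK (416 ± 23.03 to 573 ± 20.2 FPKM), HIST1H2AC (37.5 ± 3.66 to 59.2 ± 6.53 FPKM) and HIST1H2AG (8.60 ± 1.15 to 12.6 ± 0.20 FPKM) rose, and HIST1H2AH fell (12.6 ± 1.80 to 7.19 ± 0.76 FPKM). Histone genes are near-identical copies, and their values are uncertain. Adjusted over the list alone, the higher and lower members were 5 and 1 for S phase, 0 and 0 for G2 and M phase, 1 and 0 for p53 targets, 7 and 1 for apoptosis, 0 and 1 for MYC targets and 5 and 3 for histones. Over all genes tested without control replicate 3 they were 8 and 3 for apoptosis, 0 and 4 for MYC targets and 6 and 4 for histones.

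Interferon-stimulated genes held 3 higher and 1 lower member of 26 (camera adjusted p = 0.0845). The list passed upwards without control replicate 3 (0.0491, with 7 higher and 1 lower) and under quantile normalization (0.0431), against 0.533 with an estimated correlation in the main setting. IRF1 (14.1 ± 2.204 to 26.8 ± 1.12 FPKM), the peptide transporter gene TAP1 (22.3 ± 4.65 to 39.6 ± 2.29 FPKM) and STAT2 (29.06 ± 1.52 to 43.4 ± 4.44 FPKM) rose and USP18, an inhibitor of interferon signalling, fell from 2.15 ± 0.22 to 1.01 ± 0.18 FPKM. Of 24 genes of cholesterol synthesis and SREBP2 control, the synthesis enzymes TM7SF2 (7.24 ± 0.86 to 3.85 ± 0.40 FPKM), DHCR24 (64.8 ± 11.2 to 41.9 ± 3.30 FPKM) and LSS (43.7 ± 5.16 to 30.9 ± 1.34 FPKM) fell. LDLR, the receptor for LDL uptake, rose from 22.8 ± 2.09 to 35.07 ± 3.05 FPKM (list adjusted p = 0.0892). Of 34 extracellular matrix and adhesion genes 2 rose and 4 fell (list adjusted p = 0.149). SPARC, a collagen-binding protein, rose from 64.9 ± 3.08 to 123 ± 1.37 FPKM. Those that fell included NID1 (36.9 ± 1.67 to 23.8 ± 0.75 FPKM), COL12A1 (19.8 ± 2.07 to 11.004 ± 0.81 FPKM) and ITGA3 (8.10 ± 0.69 to 4.20 ± 0.57 FPKM). In the WNT list of 20 genes the inhibitor SFRP1 (24.1 ± 0.88 to 11.5 ± 0.38 FPKM), the cyclin CCND1 (108 ± 9.19 to 69.8 ± 3.33 FPKM) and the ligand WNT3 (4.68 ± 0.34 to 2.64 ± 0.02 FPKM) fell and WNT10B rose from 1.10 ± 0.39 to 2.73 ± 0.55 FPKM (list adjusted p = 0.205). With p adjusted over the list alone, the higher and lower members were 5 and 1 for interferon, 2 and 4 for cholesterol, 3 and 9 for matrix and 3 and 5 for WNT genes. Over all genes tested without control replicate 3 they were 2 and 8 for cholesterol, 6 and 8 for matrix and 5 and 5 for WNT genes. With no filter the cholesterol and matrix lists passed downwards (camera adjusted p = 0.0234 for both), as did the cholesterol list under quantile normalization (0.0431). With an estimated correlation in the main setting they gave 0.373 and 0.533.

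Markers of other cell types that placental material could hold were mostly below the expression filter. Of 16 stromal and decidual markers 4 were measured, and TAGLN, a smooth muscle actin-binding protein, fell from 21.3 ± 5.28 to 6.10 ± 0.42 FPKM and PDGFRB from 2.51 ± 0.18 to 0.784 ± 0.246 FPKM (list adjusted p = 0.226). Of the 22 blood and immune markers 2 were measured, and CSF1R, which trophoblast also expresses, fell from 22.8 ± 3.24 to 15.4 ± 0.75 FPKM (adjusted p = 0.0845). Endothelial markers gave 2 measured genes, of which 0 passed (adjusted p = 0.264). When adjusted over the list alone, 2 stromal markers, 2 blood and immune markers and 0 endothelial markers were lower, and 0 were higher. Without control replicate 3, 2 of the 4 stromal markers were higher and 2 lower over all genes tested, and with no filter the stromal list passed downwards (camera adjusted p = 0.0113; with an estimated correlation and the filter, 0.592). The stromal collagen gene COL3A1 lay between 0.034 and 0.060 FPKM in the 6 libraries, and PTPRC, the pan-leukocyte marker, between 0 and 0.023 FPKM.

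**Figure D2:**
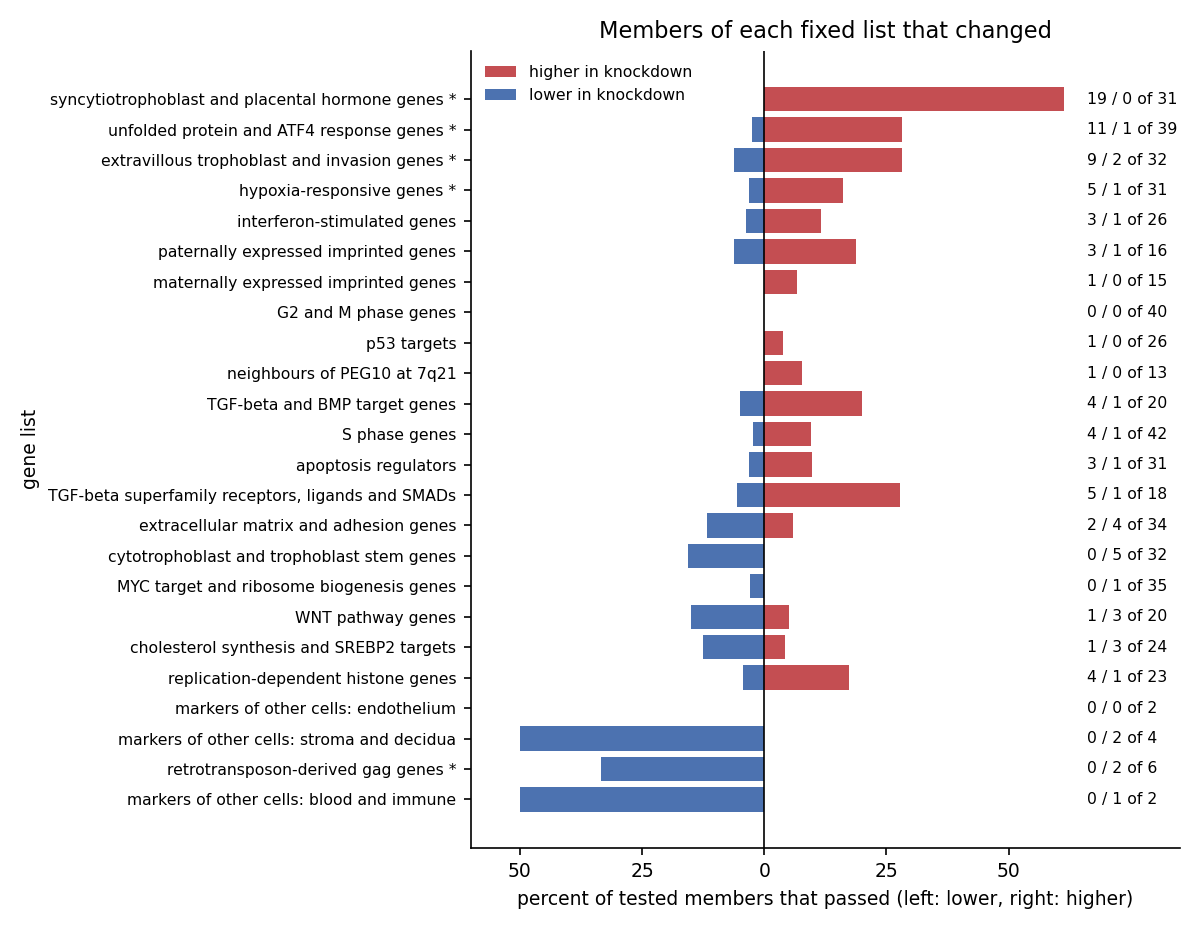
Percent of the tested members of each of the 24 fixed gene lists that were higher (red, to the right) or lower (blue, to the left) in knockdown cells at a limma adjusted p below 0.05, with the counts higher / lower of the members tested at the right. An asterisk marks the 5 lists past the threshold with camera at a preset correlation; the syncytiotrophoblast list had 19 of 31 members higher and 0 lower.

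Control replicate 3 stood apart from the other libraries. Its log2 values correlated across genes at 0.937 to 0.962 with the other 5 libraries, which correlated at 0.971 to 0.987 with one another. The log2 difference between control replicates 1 and 3 went with transcript GC content (Spearman's rho = -0.75 for 1 minus 3, across genes, which are not independent replicates), as did that between 2 and 3 (-0.77), against 0.01 between 1 and 2. Control replicate 3 minus each knockdown library gave 0.56, 0.61 and 0.59. Knockdown replicate 1 differed from knockdown replicates 2 and 3 in the same direction (0.40 and 0.36). The number of changed genes depended on the libraries used. Without control replicate 3 it was 3142, which included all 1013 genes, and it was 260 and 226 without control replicate 1 or 2 and 135, 91 and 88 without knockdown replicate 1, 2 or 3. Of the 92 named genes past the threshold, 92 kept their call without control replicate 3 and 31 to 45 without another library, PEG10, HAND1, CGA and CGB5 in each case. Among named genes, TUBA1B, HNRNPC, CCND1 and MOAP1 carry GCATGTC in the 3' UTR, a sequence more frequent among lower genes. PEG10, SGCE, SLC4A8, INSL4, SPARC, CCNE1, USP18 and PNMA1 carry TTCCACA, a second such sequence.

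**Figure D3:**
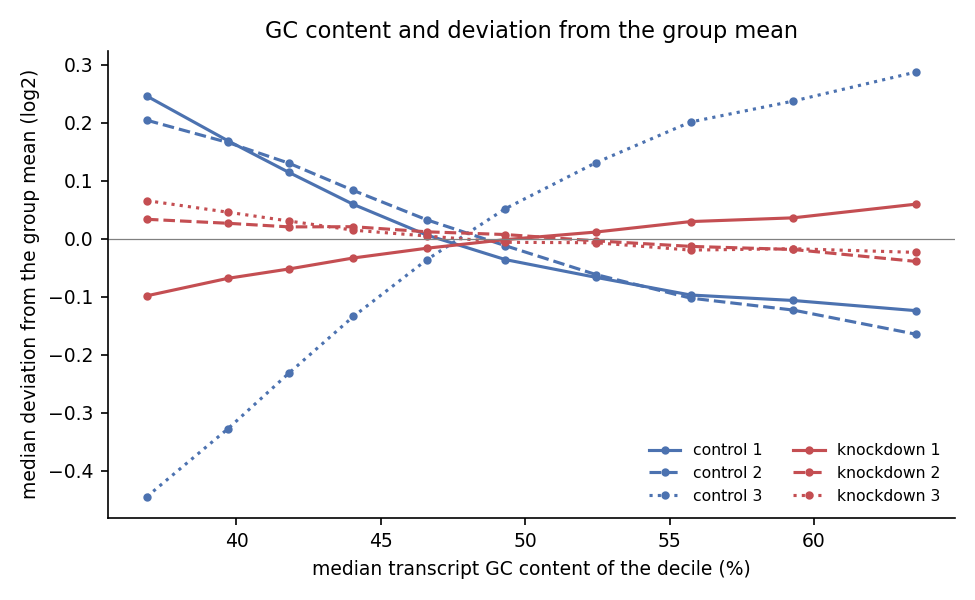
Median deviation of each library from its group mean (log2, vertical axis) in 10 equal groups of genes ordered by transcript GC content (percent, horizontal axis), with controls in blue and knockdown libraries in red and 1 line per library. The line of control replicate 3 runs from -0.44 at the lowest to 0.29 at the highest GC content, and the opposite course of the other 2 controls follows from centring on the group mean.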

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

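The GC correction, the library weights and the test without genes carrying the 7-base sequences were chosen after seeing the data. The fall of PEG10, which was kept in the last of these although it carries a sequence, passed under each alternative run, with log2 changes from -2.13 to -2.39. The number of changed genes was 1007 to 1016 with other pseudocounts, robust moderation, no trend, median-of-ratios rescaling or quantile normalization (411 higher and 599 lower with the last, which lost 143 of the 1013), and 776 with a filter at 5 FPKM. It moved to 492 without a filter (249 higher, 243 lower), to 2988 after the GC correction (1383 higher, 1605 lower; 981 of the 1013 shared), to 4233 with library weights (2343 higher, 1890 lower; 1013 shared) and to 654 without carriers of the 7-base sequences, which left 10327 genes to test (284 lower). Leaving out 1 library gave 88 (without knockdown replicate 3) to 3142 genes (without control replicate 3), 40 to 1767 higher and 48 to 1375 lower. The cause was not tested where none is named.

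With the replicate block 87 genes changed (46 higher, 41 lower), all 87 among the 1013, and the 5 list calls held. Same-numbered samples did not deviate together (correlations across genes of -0.27, -0.04 and -0.29 for numbers 1, 2 and 3). These deviations had no GC correction and carry the GC trend of control replicate 3. The check can therefore neither show nor exclude that the numbers pair the samples.

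The number of lists past the threshold, 5 in the main test, was 10 without a filter, 8 with quantile normalization, 11 with fry and 0 with an estimated correlation. Beyond the 5, the test with no filter called p53 targets (0.0159) upwards and cytotrophoblast genes (0.0113), stromal markers (0.0113), cholesterol synthesis (0.0234) and matrix genes (0.0234) downwards. Quantile normalization added interferon genes upwards and cytotrophoblast and cholesterol genes downwards (0.0431 each), and leaving out control replicate 3 added interferon genes (0.0491). In turn, fry called p53 targets (0.00411), S phase (0.0278) and apoptosis genes (0.0329) upwards, and cholesterol synthesis (0.00751), cytotrophoblast (0.0187) and blood and immune genes (0.0329) downwards. The calls stand against highest adjusted p of 0.348 for p53 targets, 0.533 for interferon and matrix genes, 0.379 for cytotrophoblast genes, 0.373 for cholesterol synthesis, 0.782 for stromal markers, 0.957 for S phase, 0.617 for apoptosis and 0.398 for blood and immune genes over the alternatives run. With an estimated correlation the adjusted p was 0.348 for the syncytiotrophoblast, unfolded protein and hypoxia lists and 0.373 for the extravillous and retrotransposon gag lists. Without carriers of the 7-base sequences, which took out both of its changed members, the gag list gave 0.167. Over single libraries left out, its adjusted p ran from 0.00358 to 0.0504 and that of the hypoxia list from 0.0274 to 0.0726.

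Directions turned in lists and genes that did not pass. Under quantile normalization these were S phase (adjusted p = 0.957) and G2 and M phase (0.923). After the GC correction they were the 7q21 neighbours (0.608), the TGF-beta superfamily (0.814), G2 and M phase (0.993) and SGCE (log2 difference -0.21), and with library weights the neighbours (0.692), the superfamily (0.904) and G2 and M phase (0.423). Over single libraries left out, where the direction turned in at least 1 case, the adjusted p ran from 0.314 to 0.718 for the neighbours, from 0.566 to 0.782 for the superfamily, from 0.203 to 0.961 for G2 and M phase and from 0.147 to 0.936 for histone genes. The log2 difference of MKI67 ran from -0.0039 (without control replicate 3) to 0.26. Of the 92 named genes past the threshold, 53 kept their call without a filter, 35 with the replicate block and 79 to 92 under the other settings that use all libraries. Genes no longer tested count here as not kept. They make up the whole loss with the filter at 5 FPKM (83 kept). Without carriers of the 7-base sequences (79 kept), 3 genes that were still tested missed the threshold.

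Depth is unknown in absolute terms. In the simulated data, whose noise was independent between genes, 34% of 1.5-fold changes were found with 3 against 3 libraries, and the share in the real data may differ.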

Other observations

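Chosen after the results were seen were the tests of control replicate 3 as the source of the hormone gene rise, of paralogs, of cell cycle exit and of GC content among abundant genes, and the genes of the next paragraph.

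Outside the naming rule, the 10 lower genes with the smallest p and a searchable 3' UTR included the following. The nucleotidase NT5C3B fell from 30.3 ± 2.92 to 9.82 ± 0.26 FPKM, the protease inhibitor SLPI from 11.9 ± 1.17 to 3.85 ± 0.38 FPKM and ENC1, an actin-binding protein, from 46.9 ± 1.12 to 19.1 ± 0.54 FPKM. The others each carry 1 or both of 2 sequences of 7 bases, GCATGTC and TTCCACA, in the 3' UTR. The sequences were found from the same fold changes, so their presence here is no separate evidence. Among the largest falls named earlier, HAND1, CRYAB, MYOZ1, ANGPTL2 and LAYN carry neither, while PEG10 and SLC4A8 carry TTCCACA. Of the carriers among the 10 genes, MTHFD1, a cytosolic folate enzyme, fell from 89.1 ± 6.21 to 31.05 ± 1.89 FPKM. The DNA methyltransferase DNMT3B fell from 145 ± 12.8 to 54.6 ± 0.82 FPKM, PIGC, which acts in GPI anchor synthesis, from 24.8 ± 0.17 to 8.36 ± 0.34 FPKM, and the 14-3-3 theta gene YWHAQ from 295 ± 33.2 to 104 ± 0.33 FPKM. CRTAP, a partner of collagen prolyl hydroxylase, fell from 58.7 ± 6.75 to 18.5 ± 0.96 FPKM and EMP2, a membrane protein, from 24.1 ± 3.46 to 7.81 ± 0.73 FPKM. Among the 10 higher genes picked the same way, PLIN2, the lipid droplet coat protein, rose from 133 ± 0.77 to 304 ± 12.8 FPKM, S100P, a calcium-binding protein of placenta, from 96.7 ± 10.96 to 221 ± 20.5 FPKM, CEACAM1, an adhesion molecule, from 1.13 ± 0.10 to 5.66 ± 0.59 FPKM, and SPRY4, an inhibitor of receptor tyrosine kinase signals, from 2.35 ± 0.44 to 8.48 ± 0.86 FPKM (limma adjusted p of at most 0.00421 for all 20 genes).

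Lower genes carried 1 sequence of 7 bases in the 3' UTR far more often than other genes. In 10589 genes (83.7% of those tested) 15728 7-mers were searched, with z values from GC-corrected fold changes. GCATGTC had the most negative z (-11.98, against -5.25 at the lowest in 100 permutations). By the calls of the main test, it stood in 104 of 481 lower genes (21.6%), 22 of 437 higher genes (5.03%) and 745 of 9671 genes that did not pass (7.70%). With the uncorrected fold changes, which were not permuted, its z was -11.72 and the most positive z of any 7-mer was 7.14. GCATGTC occurs once in the longest PEG10 transcript, at position 944 of 6618. Of the 7-mers tested, 31.6% occur at least once in some PEG10 transcript. A candidate explanation is silencing of further transcripts through the seed of the knockdown reagent, which the labels do not name. Beyond the permutations lay also AGCATGT (z -7.40), CATGTCT (-6.54) and CATGTCA (-5.89), which overlap GCATGTC. So did TTCCACA (-5.94) with the overlapping TCCACAT (-5.86) and TTTCCAC (-5.67). The most positive z of any 7-mer was 6.25, also beyond its permutations (5.04). A z no further from 0 than 6.25, as for CATGTCA, TTCCACA, TCCACAT and TTTCCAC, is therefore not specific alone. AGCATGT and CATGTCT lay further from 0, but their sites are in part those of GCATGTC. While GCATGTC or TTCCACA stood in 195 of the 481 lower genes (40.5%), in 21.3% of those that did not pass and not in HAND1, silencing through other sites and indirect effects were not tested and stay open, and regulation of the same genes by a microRNA or by PEG10 itself was not tested.

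The rise of syncytiotrophoblast genes had a median of 0.84, and GC content, control replicate 3 and paralogs did not account for it. The median was 0.88 after the GC correction and 0.82 without control replicate 3, and among the 22 members with no near-identical paralog it was 0.93, with 16 of them (72.7%) higher. Syncytial differentiation with withdrawal from the cell cycle would lower both cell cycle lists. Their medians were 0.0498 for S phase, the lower of them, and 0.12 for G2 and M phase (0.0048 and -0.045 without control replicate 3). Neither median lay below -0.3, the bound set for a broad withdrawal after the results were seen. The SD over members was 0.38 in either list, which is a spread between genes and not the uncertainty of a median. A smaller or partial cell cycle exit stays open, since single genes went both ways. Without control replicate 3, 10 S phase genes were higher and 7 lower, and 2 G2 and M phase genes were higher and 9 lower. CDKN1A was higher there (0.61), while with all libraries fry called the S phase list upwards (adjusted p = 0.0278). The effect of PEG10 loss and an indirect seed effect also stay open, since the labels give 1 knockdown group.

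Control replicate 3 differed from the other controls 1.72 times as much as these differed from each other (ratio of SDs of log2 differences). After the GC correction the ratio was 1.34, in line with a GC bias in that library. Among the 1098 genes with at least 100 FPKM the ratio was 4.07, where low depth would have brought it near 1, so its lower relative depth is not the source; it remained at 2.69 there after the correction, so GC content is not the whole cause among abundant genes. With all libraries the log2 change fell with GC content across genes (Spearman's rho = -0.30), and without this library rho was 0.04. A difference in handling of this sample was not tested, and no label gives a batch.

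The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1013 changed genes and the highest of the others 6, so that 1 of 10 splits gave as many. For gene lists the real split gave 5 and the highest of the others 6, and 3 of 10 splits gave at least 5.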
